A study of Mus musculus with 20 samples.

How the data were processed

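The series holds 20 mouse cDNA arrays with 2 channels each. Per the labels, one channel held amplified RNA from a brain region of a mouse with a null mutation, and the other held pooled RNA of the same region from wild-type mice. The 4 regions were cortex, hippocampus, cerebellum and brain stem-diencephalon, with 5 arrays each. On 3 arrays of each region the labels put the null RNA in channel 1, and on 2 arrays, called dye swaps, in channel 2. The labels do not say whether arrays with different numbers came from different animals, so the p-values measure the spread between these samples, which may be technical.

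The deposited values are log ratios of the 2 channels that the authors had already centred near 0, and they were read as log2 values. The base of the log and the order of the channels are not given in the sources used here. The deposited extremes reached -5.06 and 5.48, and the medians per array lay between 0.00862 and 0.0609. Between 6793 and 13963 of the 15245 probes had a value on an array, and the rest were empty. Signal and background of the channels were not analysed here, and the number of arrays limits the precision.

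The dye swaps were checked before any gene was tested. After the mean of each orientation was removed, arrays of one region with opposite orientation correlated across probes at -0.237 in cortex, -0.215 in hippocampus, -0.294 in cerebellum and -0.17 in brain stem-diencephalon. Before that removal, pairs of opposite orientation within a region had a median correlation of -0.285 over 16 pairs, but 0.122 over the 8 pairs with a channel 1 array of number 1. The deposited ratios were read as ratios by channel on the values after the removal, and the swapped arrays were multiplied by -1. That channel 1 stands over channel 2 is only likely, from the order in the labels. If the order is the opposite, every sign given for the null mutants turns.

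Each array was centred on its median. A probe entered with a value on at least 3 arrays of every region and on at least 1 array of each orientation in each region. Of the 15245 probes, 9604 had a single gene symbol, 213 had several and 5428 had none in the tables used here, and 9496 of the single symbols matched a current mouse gene by Entrez ID. The filter kept 9701 probes. Probes of a gene were averaged, which gave 8319 features, 5255 of them genes and 3064 probes without a single gene name. The reference annotation was used for names only, on the mouse assembly GRCm38.p6.

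Arrays of a region that share a number were averaged as 1 replicate. This gave 4 replicates in cortex, where a swapped array without a number stood alone, and 3 in each other region, 13 in all. The labels do not say which extract the unnumbered array held. It may repeat a numbered cortex extract, so the counts of 4 and 13 may be too high. A linear model per feature held a term per region and a term for the orientation of the arrays averaged, and its variances were moderated with limma 3.58.1 in R 4.3.3 (prior degrees of freedom 6.04, residual degrees of freedom 8 for a complete feature). Each region's ratio and the mean of the 4 ratios were tested against 0. The pooled wild-type RNA is the only control, and its own spread is left out. Regions were compared by an F test of equality and by the 6 pairwise differences. All p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and are those of limma's moderated test unless another test is named. Calls shared by regions were tested with one-sided hypergeometric tests.

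Gene lists were tested with limma's camera at a preset correlation of 0.01. On the 5468 features without a missing replicate, camera with an estimated correlation and fry were run beside it. The lists covered acid-base transporters, the vacuolar proton ATPase, sodium and calcium pumps and exchangers, voltage-gated cation channels, glutamate signalling, GABA and glycine signalling, the synaptic vesicle cycle, neuropeptides, immediate early genes, chaperones and ER stress, apoptosis, the cell cycle, oxidative phosphorylation, glycolysis, ribosomal proteins, the proteasome, cholesterol synthesis, and the cytoskeleton with signalling genes, called the cytoskeletal list. Further lists held markers of myelin and oligodendrocytes, astrocytes, microglia, vessels and erythrocytes, choroid plexus and meninges, and neurons of the cerebellum, the forebrain, and the brain stem and diencephalon. Lists with fewer than 5 measured genes were not tested, which left 22 tested lists.

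The design, the filter, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. Per region the rule named the 12 highest and 12 lowest genes past the threshold with one sign in every replicate. For the mean it named the 8 highest and 8 lowest with one sign in all 4 regions, for differences the 8 genes with the smallest p of the F test, and for each list up to 4 genes with the smallest p. RIKEN clones, predicted gene models and expressed sequences counted but were not named. Alternatives covered the centring, scaling between arrays, the orientation term, the treatment of swapped arrays, the filter, the replicate number as a block, single replicates left out, the moderation and the threshold. The alternatives without the repeated array and without the channel 1 arrays of number 1 were chosen after seeing the data. A planned result on a single gene is not reported here.

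The model was tested on simulated data with the same missing values. A log2 change of 1 was recovered for 95.5% to 100% of changed features in a region, and a change of 0.5 for 35.8% to 50.7%. For the mean of the regions 97.0% of changes of 0.5 were recovered. Between 4.85% and 6.6% of the calls were false, and with nothing changed the model made at most 1 call. The simulation drew its noise independently for each region and replicate, with the same change in every region. It held no correlation between regions by number, no repeated array and no deviating arrays. These shares may therefore not hold for the data, above all for the mean of the regions.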

Results

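The arrays compared the RNA of 4 brain regions of mice with a null mutation with pooled wild-type RNA of the same region. Cortex had 4 replicates, and hippocampus, cerebellum and brain stem-diencephalon had 3 each. The swapped cortex array without a number was counted as a replicate of its own, but it may repeat a numbered extract. Between 6793 and 13963 probes had a value on an array, and the number of arrays limits the precision. One swapped array appeared nearly unchanged under 2 regions, as number 1 of cerebellum and number 2 of brain stem-diencephalon. These 2 copies correlated at 0.9952 over 6748 probes, and 82.1% of the differences lay within 0.001 of their median of 0.00259, while the next highest correlation among the 190 pairs of arrays was 0.743. Which region the array came from is not given in the sources used here, so counts for both regions are also given without it. Directions are given as null over wild type and are likely only, because the order of the channels in the ratio is not stated.

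**Figure D1:**
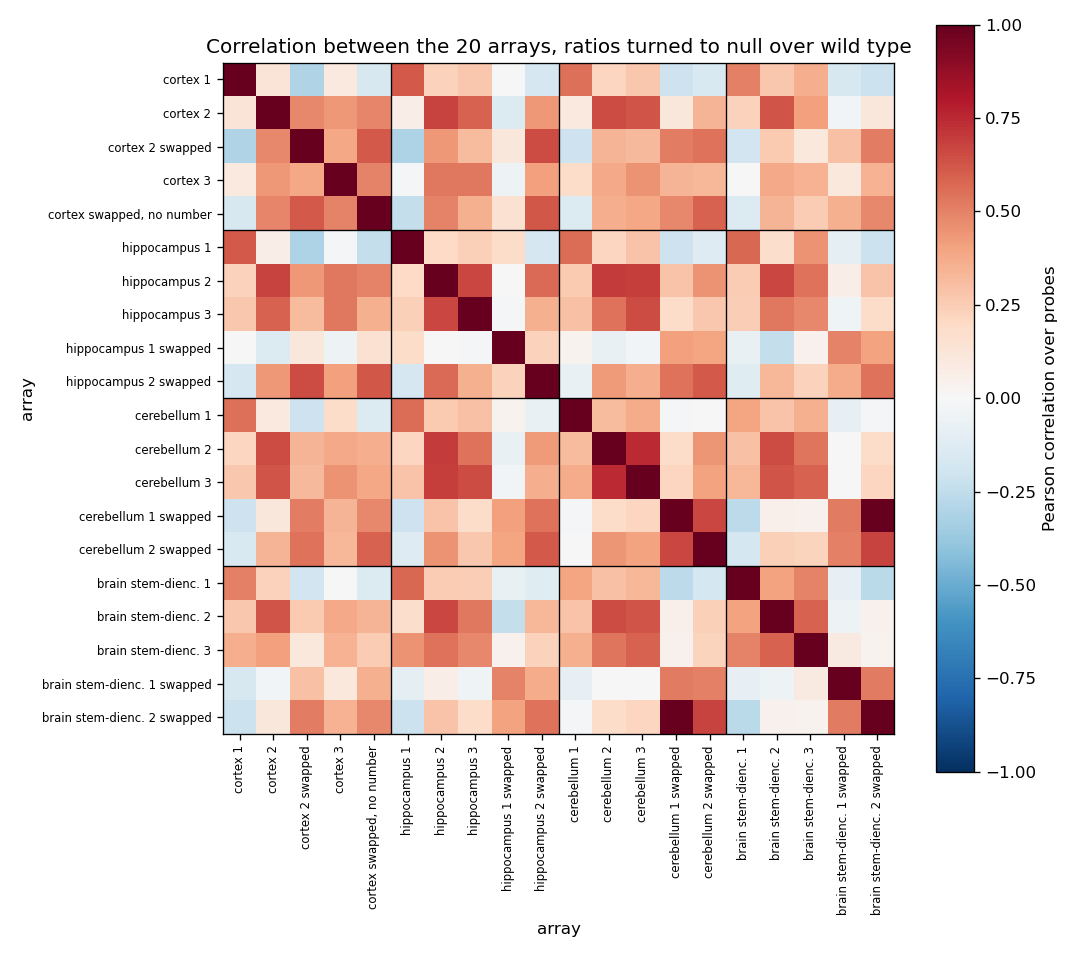
Pearson correlation over probes between the 20 arrays, with swapped arrays multiplied by -1 and black lines between regions; the axes list the arrays and the colour bar gives the correlation. The array deposited under 2 regions shows as a pair with a correlation of 0.9952, and the 4 channel 1 arrays of number 1 correlate at 0.395 to 0.614 with each other.

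The mean over the 4 regions asked which genes differed between null and wild-type RNA across the brain. The Y-linked gene Eif2s3y lay off 0 on every array with a value. It was at -1.36 to -0.437 on the number 1 arrays, 0.935 to 1.64 on the others and 1.71 on the repeated array. The null mice and the wild-type pool may therefore differ in sex, and such an effect cannot be told apart from that of the mutation. The 13 replicates of the mean may not be independent. Replicates of one number correlated between regions after the fit, mostly above 0 (-0.189 to 0.732). The repeated array was counted in both cerebellum and brain stem-diencephalon. The SE and p-values of the mean may therefore be too small. Counts with the replicate number as a block are given below. Rbm3, which codes for a cold-inducible RNA-binding protein, was likely higher in the null mutants by 1.53 ± 0.08 on the log2 scale (SE, n = 13), which is 2.88-fold, in 13 of 13 replicates (adjusted p = 1.4e-07). Cirbp, the related cold-inducible RNA-binding protein, rose by 0.47 ± 0.06 in 12 of 12 replicates with a value (adjusted p = 0.000358). Among the lowest genes, Jag1, which codes for a Notch ligand, fell by 1.78 ± 0.10 on the log2 scale (3.43-fold, n = 12, adjusted p = 6.15e-07). Slc16a13, of the monocarboxylate transporter family, fell by 2.06 ± 0.21 (4.17-fold, n = 12), and Fbxw24, of the F-box family, fell by 2.22 ± 0.24 (4.65-fold, n = 10). Msantd1, Xpo4, an exportin, Khdc1b, and Pabpn1, a nuclear poly(A)-binding protein, fell to -1.99, -1.79, -1.73 and -1.37 and were lower in every replicate with a value. Jag1, Msantd1, Xpo4 and Khdc1b shared one profile over the replicates, as described below, and may not be separate results or readings of these genes. Pisd-ps3 fell by 0.92 and was lower in 10 of 12 replicates.

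The other genes named as highest were the transcription factors Nfix (0.92) and Tcf4 (0.80), tyrosine hydroxylase Th (0.67), which makes the precursor of the catecholamines, Fam126b (0.67), the cytoskeletal adaptor Epb41l1 (0.65), the phosphodiesterase Pde8a (0.62) and the cohesin subunit Rad21 (0.61). Probes of one gene did not always match. A second probe of Slc16a13 that missed the filter had a median of 0.164 over 14 arrays, against -2.06 for the probe tested, a second probe of Pabpn1 had -0.472 against -1.26, and a second probe of Tcf4 had -0.281 against 1.06. Other probes of Xpo4 and Khdc1b that missed the filter had -0.166 and 0.0661 on 9 arrays each, where the probes tested had -2.59 and -2.09. Probes that were averaged could differ too, as for Emc8, with 0.77 and 0.164 in the mean of the regions. In all, 2172 of 8319 features passed the threshold (1097 higher, 1075 lower), of which 1411 were genes with a symbol, and 69 reached 1.5-fold. The count was 1407 without the repeated array, 944 without the unnumbered cortex array, 1333 without hippocampus replicate 2, 1370 without cerebellum replicate 2 and 1374 without brain stem-diencephalon replicate 2.

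**Figure D2:**
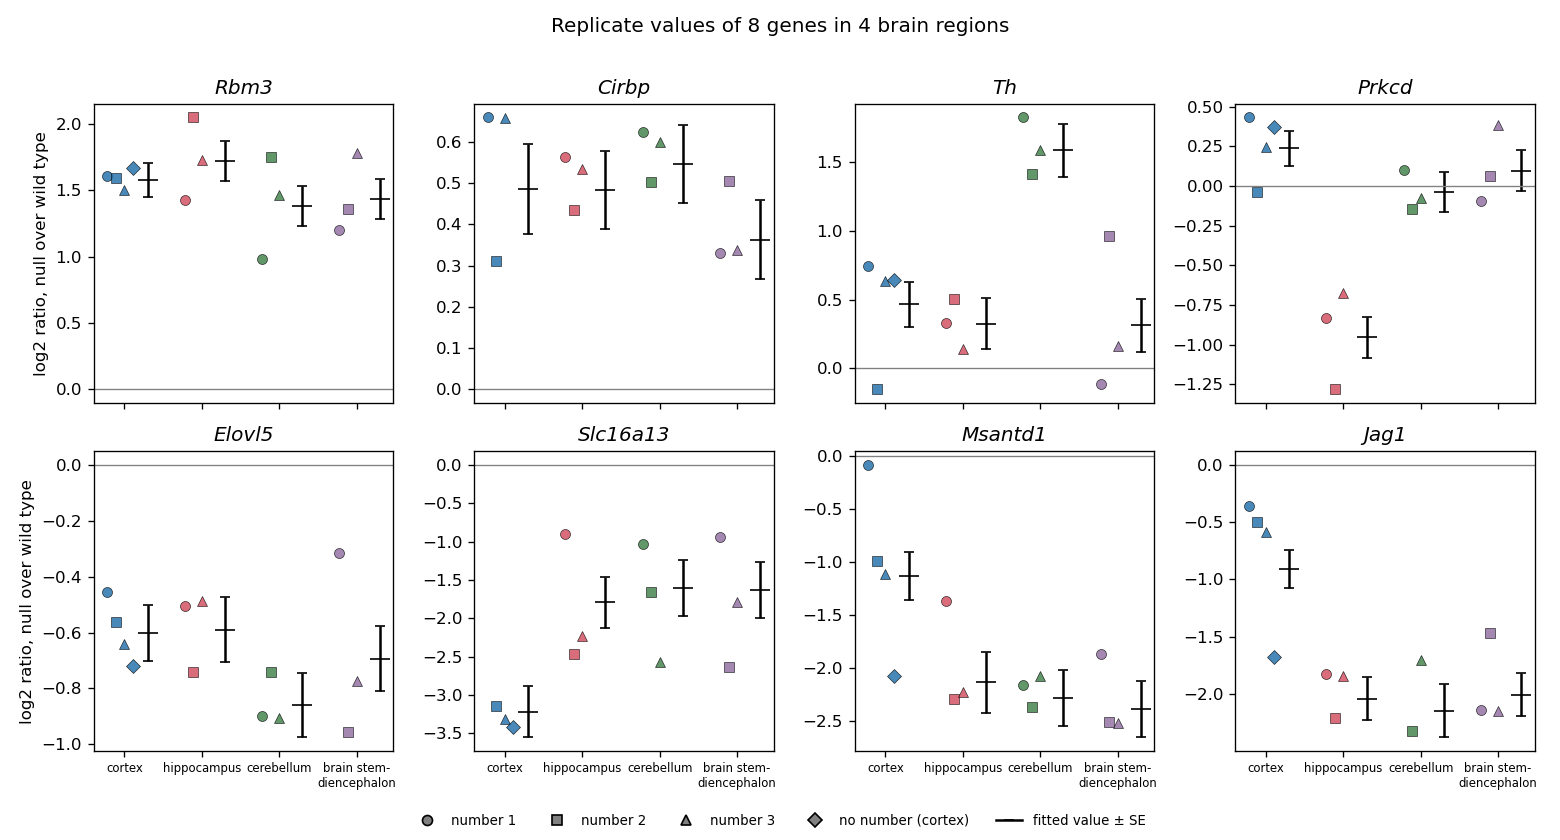
Log2 ratios of null over wild type for 8 genes (vertical axes, a scale per gene) in each replicate of the 4 regions (horizontal axes), with symbols for the replicate number and a bar for the fitted value ± SE, which also takes out the orientation of the arrays and so can lie beside the points. Rbm3 lies above 0 in all 13 replicates, and Th is highest in the cerebellum with a fitted value of 1.58.

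In cortex, Rbm3 was likely higher by 1.58 ± 0.13 (SE, n = 4), or 2.98-fold, and Slc16a13 and Fbxw24 fell to -3.22 ± 0.33 (n = 3) and -3.21 ± 0.38 (n = 2), or 9.30-fold and 9.27-fold. Ciart, a repressor of the circadian clock, rose by 0.89 ± 0.13 (n = 4), and Fxyd6, of the family that regulates the sodium pump, rose by 0.82 ± 0.15. Pdia4, a disulfide isomerase of the endoplasmic reticulum, fell by 1.01 ± 0.20 (n = 4), and Gsr, which reduces glutathione, fell by 0.90 ± 0.17. The other named genes that rose were Golph3l, Ncapg, Septin7, Fbxo34, Orc6, Atp6v1b2, Lin54, Tmem254a and Cetn4, by 0.66 to 0.86, and those that fell were Pabpn1, Msantd1, Khdc1b, Ptp4a3, Zbtb18, Agpat1, Fam220a and Jag1, with values from -1.39 to -0.91.

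By gene group, 6 of 24 measured genes of the list of cytoskeletal and signalling genes changed in cortex (2 higher, 4 lower), or 12 adjusted over the list alone (2 higher, 10 lower). Among them the tubulin Tubb3 had -0.80 ± 0.17, the adaptor protein Ywhag -0.73 ± 0.16 and Marcksl1 -0.53 ± 0.08. The list missed the threshold (median -0.13, adjusted p = 0.0518, and adjusted p = 0.282 with an estimated correlation). Of 30 chaperones and genes of ER stress 3 fell (5 changed adjusted over the list alone), with Hsph1 and Stip1 at -0.73 and -0.54 beside Pdia4 (adjusted p of the list = 0.0614, and adjusted p = 0.671 with an estimated correlation). Of 10 subunits of the vacuolar proton ATPase Atp6v1a and Atp6v1b2 rose, by 0.63 and 0.68 (3 changed adjusted over the list alone). Of 9 genes of the synaptic vesicle cycle Nsf and Synj1 rose, by 0.53 and 0.49, while Cltb fell by 0.43 (4 changed adjusted over the list alone).

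In cortex 343 features passed (140 higher, 203 lower; limma), of which 227 were genes with a symbol and 110 reached 1.5-fold. The higher features made up 40.8% of the calls, 52.2% with the values as deposited and 21.6% after arrays were scaled to one spread, which left 37 calls. Single replicates moved the count strongly. It was 6 without the unnumbered array, 56 without cortex replicate 2, 31 without replicate 3 and 1689 without replicate 1. It was 862 and 203 without hippocampus replicates 1 and 2, 116 and 159 without cerebellum replicates 2 and 3, and 164 without brain stem-diencephalon replicate 3. The regions share one estimate of the spread and one orientation term per feature, and which of these moved the count was not tested. With a variance trend and robust moderation the count was 29.

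In hippocampus, Rbm3 was likely higher by 1.72 ± 0.15 (SE, n = 3), or 3.28-fold, and Cirbp rose by 0.48 ± 0.09. Prkcd, which codes for protein kinase C delta, fell by 0.95 ± 0.13 (n = 3, adjusted p = 0.00218) in 3 of 3 replicates, and Ppp1r1b, a phosphatase inhibitor of dopamine-responsive neurons, fell by 0.63 ± 0.12. Ppp3ca, the catalytic subunit of calcineurin, rose by 0.61 ± 0.10, and Fth1, the heavy chain of ferritin, by 0.44 ± 0.09. Pfdn5, Tmem254a, Rps19 and Rpl6 rose by 0.41 to 0.64. Xpo4, Msantd1, Jag1, Fbxw24, Slc16a13 and Khdc1b had values from -2.30 to -1.76, and Ypel2, the cadherin Fat1, Cdk18 and Spred1 from -0.82 to -0.60.

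Ribosomal protein genes lay higher as a group in hippocampus. Of 63, 60 had a value above 0 (median 0.167, adjusted p = 4.19e-12), 2 rose and 13 rose adjusted over the list alone, but adjusted p = 0.115 with an estimated correlation. Of 35 genes of the proteasome and ubiquitin list 29 lay above 0 (median 0.182, adjusted p = 0.000105, and adjusted p = 0.0262 with an estimated correlation), while 0 passed with limma over all features and 2 rose adjusted over the list alone. The cytoskeletal list lay lower (median -0.203, 15 of 24 genes below 0, adjusted p = 0.00196, and adjusted p = 0.0262 with an estimated correlation), with 1 gene called, Marcksl1, at -0.55 ± 0.10, and 8 lower adjusted over the list alone. The 5 myelin genes lay at a median of -0.235 (adjusted p = 0.0225), with 0 called by limma over all features and 2 lower adjusted over the list alone. The 6 vessel and erythrocyte genes lay at -0.294 (adjusted p = 0.0397), with 1 called and 3 adjusted over the list alone. In that list Pecam1, an endothelial adhesion molecule, fell by 0.53 ± 0.10, while haemoglobin Hbb-b1 had a value of 0.53. These 2 lists had too few complete genes for an estimated correlation, and without the channel 1 arrays of number 1 their adjusted p was 0.0503 and 0.0668.

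In hippocampus 55 features passed (13 higher, 42 lower), 29 of them genes with a symbol, and 38 reached 1.5-fold. The count was 13 and 19 without hippocampus replicates 2 and 3, 35 and 36 without cerebellum replicates 2 and 3, and 36 without brain stem-diencephalon replicate 3, and 17 with a variance trend and robust moderation. The call of Fbxw24 ended without the repeated array (adjusted p = 0.0543).

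In cerebellum, Th was likely higher by 1.58 ± 0.19 (SE, n = 3) in 3 of 3 replicates (adjusted p = 0.000935), and Rbm3 rose by 1.38 ± 0.15, or 2.60-fold. Both calls held without the repeated array, with adjusted p = 0.00103 and 0.00212. Fbxw24, Msantd1, Jag1, Khdc1b and Xpo4 had values from -2.31 to -1.96, Oog3 fell by 0.95 ± 0.12, and Car7, a carbonic anhydrase, fell by 0.79 ± 0.12 (n = 3), and these calls also held without that array. The calls of the following genes ended without it. Nfix, Rad21, the glucose transporter Slc2a4, Cdk8, Rtel1, Bnc1, Epb41l1, Emc8, Fam214a and Rspo2 had values from 0.72 to 1.21, and Pabpn1, Slc16a13, Magi3, Entr1, Ttr and Pogz from -1.71 to -0.99. Ttr, which codes for transthyretin of the choroid plexus, fell by 1.05 ± 0.21 with the array and had a value of -0.74 without it (adjusted p = 0.321).

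Ribosomal protein genes lay higher in cerebellum (54 of 63 above 0, median 0.163, adjusted p = 8.56e-07), with 5 rising and 15 rising adjusted over the list alone, but adjusted p = 0.248 with an estimated correlation. The 7 microglial and immune genes all lay above 0 (median 0.38, adjusted p = 0.0041), with C1qa at 0.58 ± 0.16, C1qb at 0.43 ± 0.12, Ctsd at 0.40 ± 0.13 and C1qc at 0.38 ± 0.12. None passed over all features (0 with limma), 5 were higher adjusted over the list alone, and adjusted p = 0.248 with an estimated correlation. Genes of oxidative phosphorylation lay lower (33 of 42 below 0, median -0.146, adjusted p = 0.00597), with 1 gene called, Cox8a, at -0.85 ± 0.17, and 3 lower adjusted over the list alone. The estimated correlation gave adjusted p = 0.332. Chaperones (median -0.104) and the cytoskeletal list (median -0.18) lay lower, each with adjusted p = 0.0221, but with an estimated correlation adjusted p = 0.545 and 0.248. The genes called were Dnajb1 of the chaperones (-0.45 ± 0.10) and Ywhag (-0.81 ± 0.19) and Marcksl1 (-0.47 ± 0.10) of the cytoskeletal list, and 2 and 4 genes were lower adjusted over the list alone. Scaling to one spread ended both of these list calls (adjusted p = 0.0595), testing complete features alone ended that of the chaperones (adjusted p = 0.0651), and the cytoskeletal call also ended without the repeated array (adjusted p = 0.107). The calls of Cox8a, Dnajb1, Ywhag and Marcksl1 in cerebellum ended without it too (adjusted p = 0.0945, 0.16, 0.169 and 0.0952).

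In cerebellum 255 features passed (124 higher, 131 lower), of which 149 were genes with a symbol and 105 reached 1.5-fold. Without the repeated array the count was 48 (10 higher, 38 lower). It was 52, 20 and 27 without cerebellum replicates 1, 2 and 3, 414 without cortex replicate 1, 137 without the unnumbered cortex array, 456 and 153 without hippocampus replicates 1 and 2, and 99 without brain stem-diencephalon replicate 3. With a variance trend and robust moderation it was 25.

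In brain stem-diencephalon, Rbm3 was likely higher by 1.43 ± 0.15 (SE, n = 3), or 2.69-fold, in 3 of 3 replicates. Msantd1, Xpo4, Khdc1b and Jag1 fell to -2.39, -2.08, -2.06 and -2.01, Oog3 to -0.94 ± 0.12, and Ighm, the heavy chain of immunoglobulin M, to -0.78 ± 0.12. Herc1, a ubiquitin ligase, Klhl24 and Rpl17-ps5 rose by 1.10, 0.81 and 0.60, and the repressor Zbtb18, the fatty acid elongase Elovl5 and Fat1 fell to -0.94, -0.69 and -0.59. The calls of these last 6 genes ended without the repeated array, with adjusted p from 0.0573 to 0.202.

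Ribosomal protein genes lay higher in brain stem-diencephalon (59 of 63 above 0, median 0.162, adjusted p = 5.23e-09), though 0 passed over all features with limma, 2 rose adjusted over the list alone, and adjusted p = 0.192 with an estimated correlation. The proteasome list had a median of 0.126 (25 of 35 above 0, adjusted p = 0.0207, and adjusted p = 0.104 with an estimated correlation). The cytoskeletal list had a median of -0.171 (adjusted p = 0.0449, and adjusted p = 0.192 with an estimated correlation), and its call ended without the repeated array (adjusted p = 0.186), after scaling to one spread (adjusted p = 0.0864) and on complete features alone (adjusted p = 0.0832). No gene of these 2 lists passed over all features (0 with limma), and adjusted over the list alone 0 and 2 did.

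In brain stem-diencephalon 30 features passed (4 higher, 26 lower), 13 of them genes with a symbol, and 29 reached 1.5-fold. The count was 25 without the repeated array (1 higher, 24 lower), 18 and 17 without brain stem-diencephalon replicates 2 and 3, and 16 with a variance trend and robust moderation.

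Whether the change of a gene differed between regions was tested directly. Prkcd was 1.19 ± 0.17 higher in cortex than in hippocampus (values 0.24 and -0.95, adjusted p = 0.0405), and Cst3, the protease inhibitor cystatin C, had a difference of -0.79 ± 0.13 between cortex and cerebellum (values -0.42 and 0.36, adjusted p = 0.0442). Th was 1.27 higher in cerebellum than in brain stem-diencephalon, which failed the adjustment with the repeated array in both regions (adjusted p = 0.999) and passed without it (1.56, adjusted p = 0.0282), while the calls of Prkcd and Cst3 ended without it although the differences of 1.19 and -0.82 were no smaller (adjusted p = 0.059 and 0.0796). Ttr had values of -0.70, 0.68, -1.05 and -0.19 in cortex, hippocampus, cerebellum and brain stem-diencephalon, and C1qb -0.33, -0.46, 0.43 and -0.01. Their F tests had adjusted p = 0.209 and 0.218.

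The F test over the 4 regions passed for 0 features with limma, with 351 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0628, for Prkcd. Tbc1d9b, Jag1 and Zfp462 completed the 8 genes with the smallest p, with adjusted p of 0.396, 0.396 and 0.524, and Cst3 and Th had 0.23 and 0.412. The F test passed for 5 features without cortex replicate 1, 2 without cortex replicate 2, 1 without brain stem-diencephalon replicate 2 and 1 without the repeated array. With the replicate number as a block, a pairing that the labels do not give, its counts were higher and are given below. Of the pairwise differences, cortex against hippocampus passed for 1 feature and cortex against cerebellum for 4, 3 of them probes without a gene name. The other 4 pairs passed for 0 features with limma, with 238 to 488 features at an unadjusted p under 0.05. Without the repeated array cortex against hippocampus passed for 0 features, cortex against cerebellum for 3, and hippocampus against cerebellum and cerebellum against brain stem-diencephalon for 2 each.

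Calls were compared between regions. Rbm3 rose in all 4 regions, and Jag1, Msantd1, Khdc1b and Elovl5 fell in all 4, with Elovl5 at -0.60, -0.59, -0.86 and -0.69 in cortex, hippocampus, cerebellum and brain stem-diencephalon. They were the named genes among 12 features called in all 4 regions in one direction (1 higher, 11 lower). Jag1, Msantd1, Khdc1b and Xpo4 shared one profile over the replicates with 9 unnamed features, as described below. These features may not be separate results. Cirbp, Rpl6 and Tmem254a rose in 3 regions, and Slc16a13, Fbxw24, Xpo4, Marcksl1, Fat1, Oog3, Zbtb18, Rph3a and Smad1 fell in 3. Rph3a and Smad1 lie outside the rule for named genes and were chosen after their values were seen. Without the repeated array Elovl5 missed the threshold in brain stem-diencephalon (adjusted p = 0.0704). So did Cirbp, Rpl6, Tmem254a, Slc16a13, Marcksl1 and Zbtb18 in cerebellum, Fbxw24 in hippocampus, and Zbtb18 and Fat1 in brain stem-diencephalon, with adjusted p from 0.0543 to 0.202. Of 547 features called in at least 1 region 460 were called in exactly 1, and 486 (88.8%) had one sign in all 4.

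For hippocampus and cerebellum 33 lowered features were shared, against 0.661 for independent lists (one-sided hypergeometric adjusted p = 2e-52), and for cortex and cerebellum 20 raised features against 2.09 (adjusted p = 1.97e-14). All 12 tests, over 6 pairs and 2 directions, passed the threshold, but the regions share one estimate of the spread and one orientation term per feature, so their calls are not independent and the p-values may be too small, which was not tested. Lowered features that share one profile were also counted one by one in these tests. Across features the log2 ratios of 2 regions correlated at 0.619 to 0.771, where features are not independent replicates. The highest value, for cerebellum and brain stem-diencephalon, which both hold the repeated array, was 0.711 without it. Part of this may come from wild-type animals or probe effects shared by the regions. Without the repeated array 11 features were called in all 4 regions. The count was 20 without cortex replicate 1, 4 without replicate 2, 4 without replicate 3, 3 without the unnumbered cortex array, 21 without hippocampus replicate 1 and 6 without cerebellum replicate 2.

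Over the mean of the regions, 27 of 63 ribosomal protein genes rose and none fell (0 lower; 30 rose adjusted over the list alone), with Rpl6, Rps14 and Rpl3 higher by 0.36, 0.34 and 0.33 in 13 of 13 replicates each. The list's median was 0.127 (adjusted p = 5.45e-08, but adjusted p = 0.262 with an estimated correlation). In cortex its median was -0.00126 although its test pointed up (adjusted p = 0.242), and the median was 0.0146 without centring and 0.0192 after scaling to one spread. On the arrays of cortex the median ran from 0.187 on number 1 to -0.109 on the unnumbered array. Of 35 genes of the proteasome list 10 rose, both over all features and adjusted over the list alone (median 0.0886, adjusted p = 0.0128, and adjusted p = 0.0805 with an estimated correlation), with Psme1, an activator subunit, at 0.37 ± 0.07 and Psmc1 at 0.26 ± 0.05.

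Of 24 cytoskeletal genes 12 changed over the mean (3 higher, 9 lower), or 14 adjusted over the list alone (median -0.139, adjusted p = 0.00612, and adjusted p = 0.0805 with an estimated correlation). Tubb3 had -0.66 ± 0.11, Ywhag -0.63 ± 0.10, Marcksl1 -0.49 ± 0.05 and the small GTPase Rhoa -0.34 ± 0.05. Of 30 chaperones and genes of ER stress 10 changed (1 higher, 9 lower), or 11 adjusted over the list alone (median -0.0582, adjusted p = 0.03, but adjusted p = 0.798 with an estimated correlation), with Pdia4 at -0.79 ± 0.14 and Hsph1 at -0.63 ± 0.10. Scaling to one spread ended the call of the chaperone list (adjusted p = 0.0767), and so did testing complete features alone (adjusted p = 0.0975). The median of this list depended on the orientation of the array: in hippocampus it was 0.131, 0.0409 and 0.0409 on the channel 1 arrays and -0.185 and -0.14 on the swapped ones. That of the cytoskeletal list did so in cerebellum, with 0.0472, -0.0696 and -0.0879 on the channel 1 arrays and -0.361 and -0.185 on the swapped ones. In brain stem-diencephalon it was 0.0641, -0.0634 and -0.0795 against -0.119 and -0.358. The values of -0.361 and -0.358 are those of the repeated array. In cortex and hippocampus the medians of the cytoskeletal list overlapped between orientations.

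The other lists did not pass over the mean with all features. Genes of cholesterol synthesis had a median of -0.163 (5 of 12 lower and 1 higher, as adjusted over the list alone, adjusted p = 0.097). In that list Mvd had -0.58 ± 0.10 and Hmgcs1 -0.25 ± 0.05, averaged from probes that had -0.0096 and -0.47 on their own. On complete features alone this list passed over the mean (adjusted p = 0.0215, and adjusted p = 0.117 with an estimated correlation), in hippocampus (adjusted p = 0.0184, and adjusted p = 0.108 with an estimated correlation) and in brain stem-diencephalon (adjusted p = 0.00968, and adjusted p = 0.104 with an estimated correlation). Acid-base transporters had a median of -0.117 (3 of 12 lower and 1 higher, as adjusted over the list alone, adjusted p = 0.306). Car7 had -0.57 ± 0.07, the scaffold protein Slc9a3r1 -0.35 ± 0.07 and the calcium-binding protein Tesc -0.33 ± 0.09, while Chp1, another calcium-binding protein, rose by 0.25 ± 0.07. The vacuolar proton ATPase had a median of 0.0657 (3 higher and 2 lower of 10, as adjusted over the list alone, adjusted p = 0.731), with Atp6v1a at 0.48 ± 0.08 and Atp6v0b at -0.43 ± 0.08. Pumps and exchangers had a median of -0.06 and a mean of 0.0208 with a test that pointed up (adjusted p = 0.874), with Fxyd6 at 0.56 ± 0.09 and the sodium pump subunit Atp1b2 at -0.44 ± 0.07.

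Genes of the synaptic vesicle cycle had a median of 0.0385 (4 higher and 1 lower of 9, as adjusted over the list alone, adjusted p = 0.459), and voltage-gated channels and glutamate signalling had medians of 0.0494 and -0.0707 (adjusted p = 0.629 and 0.874). Immediate early genes had a median of -0.0499 (adjusted p = 0.874), although Ier5 fell by 0.68 ± 0.13 in cortex. Apoptosis, the cell cycle, oxidative phosphorylation and glycolysis had medians of -0.0329, 0.0132, -0.0309 and -0.0616 (adjusted p = 0.943, 0.733, 0.508 and 0.629), and the pyruvate carrier Mpc1 rose by 0.46 ± 0.06. The mean of the apoptosis list was 0.00197, opposite in sign to its median and to its test. Markers of myelin and oligodendrocytes had a median of -0.129, astrocytes 0.022, microglia 0.0623, and vessels and erythrocytes -0.159 (adjusted p = 0.215, 0.68, 0.874 and 0.303). Markers of choroid plexus and meninges had -0.0238 and cerebellar neurons 0.01 with a test that pointed down (adjusted p = 0.733 and 0.874), and the latter median was -0.0016 after scaling to one spread. In the lists not tested, no GABA or glycine gene was measured (0), the neuropeptide genes Scg3 and Trh had 0.17 and -0.05, and the forebrain genes Zbtb20 and Ppp1r1b had -0.14 and -0.19. Those of brain stem and diencephalon, Th, Rora, Hoxb8 and Nefl, had 0.67, 0.37, -0.04 and -0.05.

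**Figure D3:**
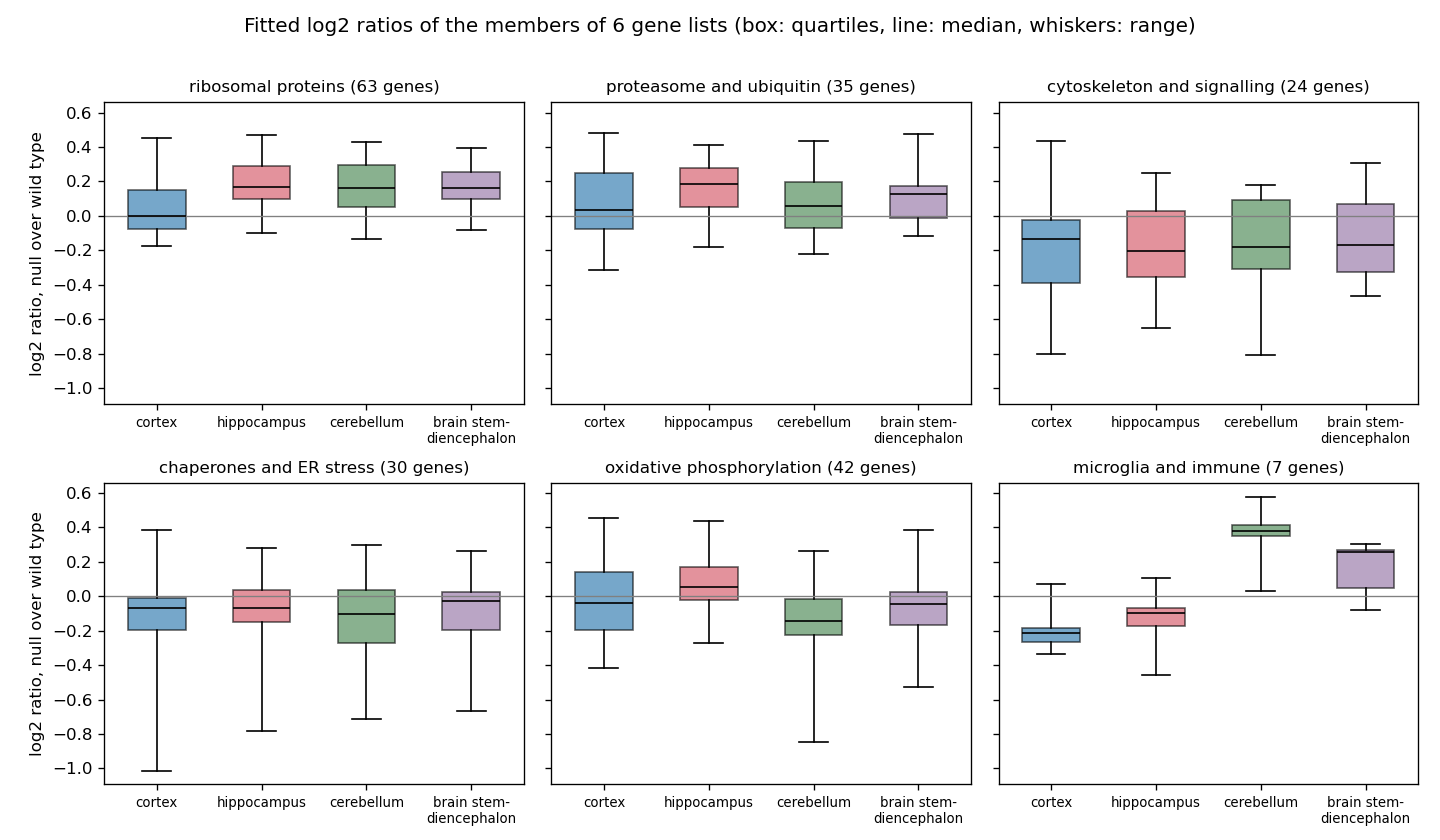
Fitted log2 ratios of null over wild type (vertical axes) for the measured genes of 6 lists in the 4 regions (horizontal axes), with boxes for the quartiles, a line for the median and whiskers for the range. The medians of the ribosomal list lie at 0.167, 0.163 and 0.162 in hippocampus, cerebellum and brain stem-diencephalon and at -0.00126 in cortex (0.0192 after scaling to one spread), and that of the microglial list is 0.38 in cerebellum.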

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

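The tests of the repeated array, of the number 1 extracts, of sex and of the shared profile were chosen only after the result was seen.

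Prkcd differed between cortex and hippocampus by 1.19 ± 0.17 on the log2 scale, and Cst3 between cortex and cerebellum by -0.79 ± 0.13, in a test of the difference itself. A further 3 unnamed probes also differed between cortex and cerebellum, with values of -2.15, -1.05 and -1.08. Splits of the replicates, with the real one included, called as many features in 4 of 35 for cortex and hippocampus (1 feature in the real split, at most 14 in the others). For cortex and cerebellum it was 2 of 35, with the real one included (4 features in the real split, at most 5 in the others). Chance could not be excluded at 0.05 for either pair. For cortex and brain stem-diencephalon the real split gave 0 features, which all 35 splits reach by construction, so the splits tested nothing there (at most 3 in the others).

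For the pairs with 3 replicates in each region the 10 splits are too few for a share under 0.05. Hippocampus and cerebellum gave 0 features in the real split and at most 0 in the others, hippocampus and brain stem-diencephalon 0 and at most 15, and cerebellum and brain stem-diencephalon 0 and at most 0. The counts of 0 with cerebellum rest on the array deposited under 2 regions, since without it each of these 2 pairs passed for 2 features. A count of 0 is reached by all 10 splits by construction, and likewise by all 100 splits drawn for the F test over the 4 regions, so neither tests chance. For the F test the highest other split gave 191, and it put all 4 replicates of number 1 into one group, which points to a structure of the samples by number.

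The values of 3 results lay far from the rest of their group by the gap to the nearest value over the range, among 12 measures of arrays and 13 genes of cortex tested, where chance marks about 1 in 20. Fbxo34 in cortex had a ratio of 0.845, with 0.199 in replicate 1 against 0.793 to 0.902 in the others. The repeated array, among those of brain stem-diencephalon, had a value for 44.64% of the probes against 75.7% to 86.21% (ratio 0.747). Its deposited SD was 0.544 against 0.282 to 0.322 (ratio 0.847).

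One array was deposited under both cerebellum and brain stem-diencephalon. Its deviations correlated at 0.204 with the cerebellum minus brain stem-diencephalon difference of the other arrays, against -0.257 to -0.134 for the other brain stem-diencephalon arrays, which argues against brain stem-diencephalon RNA. Cerebellar RNA is consistent with this value and with Th, at 1.49 on this array, 1.35 to 2.16 on the cerebellar arrays and -0.157 to 0.424 on those of brain stem-diencephalon. The evidence is modest, because the bounds of the test were also chosen after its value was seen and the channel 1 array of cerebellum number 1 itself gave -0.293. The Y-linked gene Eif2s3y, at 1.71 on this array against -1.36 to -0.437 on the other arrays of number 1 and 0.935 to 1.64 on those of other numbers, argues against an extract of number 1, although the array is averaged into cerebellum replicate 1 as deposited.

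The 4 channel 1 arrays of number 1 correlated at 0.395 to 0.614 with each other and at a median of 0.254 with the other channel 1 arrays, which correlated at a median of 0.588. A dye or hybridisation effect could give the correlation of 0.323 between their mean deviation and the dye effect estimated without them. By region it was 0.352, 0.298, 0.168 and 0.205 in cortex, hippocampus, cerebellum and brain stem-diencephalon, so this evidence is modest. The deviations of the channel 1 and the swapped arrays of number 1 correlated at 0.668 in hippocampus and 0.461 in brain stem-diencephalon. These correlations cannot decide whether the number 1 extracts differ. Both deviations are taken from arrays that share the effect of the mutation, so arrays that only show less of it would also correlate. The channel 1 and swapped arrays themselves, turned to null over wild type, correlated at 0.1848 in hippocampus and -0.0805 in brain stem-diencephalon. A lower share of mutant RNA stays open, except for Eif2s3y as given below. The ratio of values on these arrays to the other channel 1 arrays had an interquartile range of 0.365 over 32 features. Its first quartile was 0.0818, and Rbm3 had 0.781. This range cannot decide the question, since a lower share would reduce the log ratios of raised and lowered features by different factors. A difference in sex also stays open, since Eif2s3y differed by -2.24 between the number 1 and the other arrays. Without the repeated array it lay at -1.36 to -0.437 on the number 1 arrays, in both orientations, and at 0.935 to 1.64 on the others. The number 1 extracts thus differed in this transcript, and RNA of the pool mixed into them would not turn its sign. A single gene does not settle this for the other features. With arrays of one extract averaged Eif2s3y differed by -2.29 (4 against 9 replicates, which may share animals, two-sided exact permutation p = 0.0014, the smallest that the 715 splits can give). Xist differed by -0.228 (two-sided exact permutation p = 0.0713), in sign opposite to what a female animal would give. Its 2 probes stayed between -0.127 and 0.508 on the arrays with a value, so they may not read Xist and cannot decide on sex. The X-linked gene Eif2s3x, without a test, was 0.47, 0.69 and 0.76 on the channel 1 arrays of number 1 of cortex, hippocampus and cerebellum, above the other numbers of those regions, but 0.04 on the swapped array of number 1 of brain stem-diencephalon, below its other numbers (0.61 and 0.21).

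Msantd1, Jag1, Xpo4 and Khdc1b, strongly lowered in hippocampus, cerebellum and brain stem-diencephalon, shared one profile over the replicates (pairwise correlations 0.819 to 0.939). The other probes of Xpo4 and Khdc1b had a median of -0.181, with medians of -0.166, 0.0661, -0.375 and -0.197, while the strongly lowered probes had -2.59 to -2.09 on the same arrays. This argues against these 2 transcripts having fallen as read by all their probes, though the last 2 medians rest on 3 and 2 arrays. Jag1 and Msantd1 had no other probe with values. A sequence shared by these clones is a candidate explanation that stays open: 9 further features, none of them named (0), had a correlation above 0.9 with the group, but common regulation would give this too, and probe sequences were not analysed here.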

How the results depend on the processing

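The alternatives without the repeated array, with it in 1 region only, and without the channel 1 arrays of number 1 are tests chosen only after the result was seen. Counts below are of features, and the cause of a change was not tested unless it is given.

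No call of a gene named for a region or for the mean changed sign under the alternatives run for it. Genes named by the F test or by a list were not followed in those roles. The side with more calls turned under at least 1 alternative in each region and for the mean. Examples are cortex, from 140 higher and 203 lower to 188 and 172 without centring, cerebellum, from 124 and 131 to 128 and 124 without centring, hippocampus, from 13 and 42 to 22 and 16 with probes on all 20 arrays, brain stem-diencephalon, from 4 and 26 to 176 and 143 with every array as a replicate, and the mean, from 1097 and 1075 to 699 and 708 without the repeated array. The counts of 343, 55, 255 and 30 features in cortex, hippocampus, cerebellum and brain stem-diencephalon, and of 2172 for the mean, stayed within 1.5 times without centring (360, 56, 252, 31 and 2159), with probes in at least 2 replicates (268, 50, 226, 34 and 2198) and with each probe on its own (415, 53, 307, 34 and 2529). Rbm3 passed in each region and in the mean under every alternative that gave it a value. Its calls are among the 30 of 97 calls of named genes that held under every alternative run for them. Named genes were not tested with the swapped arrays taken the other way or with each probe on its own. Of 2815 values of these calls 2302 stayed past the threshold with the same sign, 513 missed it and 0 changed sign. The alternatives that ended most calls were a variance trend with robust moderation (54), the unnumbered cortex array left out (38) and cerebellum replicate 2 left out (38).

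Scaling arrays to one spread gave 37 in cortex, 142 in cerebellum, 3 in the F test and 4 called in all regions. Without the orientation term cortex had 222. With the regions fitted alone, without that term, cortex had 45, and this alternative gives no mean, F test or lists. With probes on all 20 arrays, where fewer were tested, the counts were 219 in cortex, 12 in brain stem-diencephalon, 785 for the mean, 5 in all regions and 2 lists. The variance trend, which used the mean size of the log ratio because intensities were not analysed here, with robust moderation gave 29, 17, 25 and 16 in the 4 regions, 1 in the F test and 1 in all regions. A fold of at least 1.5 left 110 in cortex, 105 in cerebellum and 69 for the mean. With the swapped arrays taken the other way cortex had 19, hippocampus 0 (limma), cerebellum 16 and all regions 0. The 200 smallest p per region shared 23. With an estimated correlation 0 of the 4 lists passed over the mean (limma's camera). On complete features camera with the preset correlation passed 4 and fry, which tests against no change and not against other genes, also 4. In both, cholesterol synthesis passed (adjusted p = 0.0215 and 0.000118) and the chaperones did not (0.0975 and 0.0517).

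With every array as a replicate, which counts extracts more than once, the counts were 1207, 500, 1451 and 319 in the regions, 3589 for the mean, 6 in the F test and 90 in all regions. With all arrays and the extract as a random block (correlation 0.378) they were 746, 183, 708 and 91, with 4 in the F test and 33 in all regions.

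Replicates of different regions share only a number, and 14 of 18 pairs of one number correlated above 0.1. With the number as a random block (correlation 0.23) the counts were 689 in cortex, 85 in hippocampus, 494 in cerebellum, 1445 for the mean, 10 in the F test and 20 in all regions. As a fixed block, without the orientation term and the unnumbered array, they were 296 in hippocampus, 836 in cerebellum, 193 in brain stem-diencephalon, 16 in the F test and 56 in all regions.

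Without the unnumbered cortex array cortex had 6, all 6 among the 343, cerebellum 137, the mean 944 and all regions 3. With 1 replicate left out at a time the counts ran from 6 to 1689 in cortex, 13 to 67 in hippocampus, 20 to 456 in cerebellum, 17 to 38 in brain stem-diencephalon, 944 to 2575 for the mean, 0 to 5 in the F test, 3 to 21 in all regions and 3 to 4 for lists. The lowest cortex count came without the unnumbered array and the highest without cortex replicate 1. Hippocampus was lowest without its replicate 2, cerebellum without its replicate 2 and brain stem-diencephalon without its replicate 3.

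Without both copies of the repeated array cerebellum had 48, the mean 1407 and the F test 1. With it in cerebellum only the F test had 4, and with it in brain stem-diencephalon only cerebellum had 46. Without the channel 1 arrays of number 1 the counts were 1558, 176, 1026 and 60 in the regions, 3 in the F test and 28 in all regions.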

Other observations

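The tests of lists between regions were chosen only after the result was seen, and the splits of those lists were set before their counts were seen.

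Differences of gene lists between regions were tested with the preset correlation over 22 lists and 6 pairs, 132 tests, of which 24 passed adjusted over all. Of these, 1 had no estimate, myelin between hippocampus and brain stem-diencephalon, because too few of its genes were complete. None of the others passed with an estimated correlation, where the lowest adjusted p was 0.0624. Microglial genes lay lower in cortex than in cerebellum (medians -0.215 and 0.38, adjusted p over all tests 1.6e-10, and adjusted p = 0.121 with an estimated correlation) and lower in hippocampus than in cerebellum (medians -0.0946 and 0.38, adjusted p = 0.0624 with an estimated correlation). Astrocyte genes also lay lower in cortex and hippocampus than in cerebellum (medians -0.0793, -0.0167 and 0.193). With an estimated correlation their adjusted p was 0.133 and 0.0624. Genes of oxidative phosphorylation had medians of 0.0566 in hippocampus and -0.146 in cerebellum (adjusted p = 0.0624 with an estimated correlation). Ribosomal protein genes had medians of -0.00126 in cortex and 0.167 in hippocampus (adjusted p = 0.686 with an estimated correlation).

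Chance could not be excluded for the list differences of cortex. Splits of the replicates, with the real one included, gave as many lists in 9 of 35 for cortex and hippocampus (2 lists in the real split, at most 5 in the others). Counted the same way, it was 6 of 35 for cortex and cerebellum (4, at most 6) and 10 of 35 for cortex and brain stem-diencephalon (2, at most 5). For the other 3 pairs the 10 splits are too few for a share under 0.05. Hippocampus and cerebellum gave 6 lists and at most 3 in the others (1 of 10 splits, the real one). Hippocampus and brain stem-diencephalon gave 6 and at most 2 (1 of 10, the real one), and cerebellum and brain stem-diencephalon 3 and at most 3 (2 of 10 with the real one).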
